A study of Mus musculus with 3 samples.

How the data were processed

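Cells of BP mouse mammary tumours were released with collagenase and hyaluronidase, frozen, enriched for CD45 and made into 10x Genomics libraries, per the labels' protocols. There were 3 libraries, from mice given vehicle, olaparib or olaparib with IRG1-IN-1, each from cells of 4 pooled tumours. The deposited matrices hold UMI counts per gene and barcode, made with Cell Ranger 8.0.1 per the file headers; STAR, Seurat and the mm10 genome are named in the submitters' processing notes. The counts are not normalised, and the lowest barcode total was 500 UMIs in each library. A further deposited matrix per library holds natural log values of 6956, 7438 and 8019 cells. Those values equalled the natural log of 1 plus the count scaled to the median number of detected genes per cell, as recomputed here from the count matrices; no source used here states the scale or the cell filter. In the cells the authors kept, the highest mitochondrial share was 29.9%, 29.8% and 29.9%, and the highest number of genes 7888, 7992 and 7998. The natural log matrices served only to define the authors' cells as an alternative; every value was computed from the counts.

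Markers, gene lists, the cell filter, the clustering settings, the rule for named genes and most alternatives were fixed before the data were examined. Barcodes with at least 200 genes, at least 400 UMIs and at most 15% mitochondrial UMIs were kept, which left 24153 of 26132. Cell Ranger's own call of barcodes came first, so cells under 500 UMIs were not seen. Scrublet, with an expected rate of 6%, marked 2 cells over all libraries, which is under 0.5%, so it had not worked and no cell was removed. Doublets therefore remain in the data, and keeping them, meant as an alternative, was the reported setting. Counts were scaled to 10000 per cell and log-transformed, and 3000 variable genes were chosen with library as batch. Mitochondrial, ribosomal, haemoglobin, immunoglobulin and T cell receptor segment genes were left out of them, as were list genes that are not markers. List genes that are also markers, such as C1qa and Trem2, could be chosen, as could unlisted interferon genes such as Ifih1. The lists were thus not wholly kept out of the clustering. Clustering of all libraries together, with no integration, used 30 principal components, 15 exact nearest neighbours and the Leiden method at resolution 1; clusters resembling T or NK cells were clustered again alone. Of 38 clusters 23 were named, from 23 marker sets. A marker counted as detected at 20 CPM or more and at least 25% of its highest cluster level, and a name needed 3 detected markers; these thresholds were set after the data had been seen. A cluster stayed unnamed when markers of another class outnumbered its own among its top 10 genes, or when its cells were shallow and none of its own markers stood there. Gene fold for that ranking was taken with 10 CPM added. Class names say only that cells resemble a type.

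UMIs were summed per class and library and divided by the class total (CPM). Each gene's log2 ratio was taken with 1 pseudo-UMI added at the mean class size, and printed ratios are of the CPM themselves. Levels have exact Poisson intervals, shares exact Clopper-Pearson intervals and ratios exact conditional intervals, all at 95% and for counting error only. With 1 library per group there was no test and no p-value. The comparisons were olaparib with vehicle, combination with olaparib and combination with vehicle, which share libraries, so none was set against another. Gene ratios and list medians were compared in classes with at least 100 cells in every library. For smaller classes, Acod1, some shares of cells with a UMI and summed levels of the interferon and MHC class II lists are given as values only. Named genes were those with at least 100 UMIs over both libraries and 50 CPM in one of them. Mitochondrial, ribosomal, haemoglobin, immunoglobulin and receptor segment genes, unnamed gene models and markers of another class were left out. Of these the 10 highest and 10 lowest log2 ratios were taken in macrophage-like and the 5 highest and lowest in neutrophil-like cells, with up to 4 members per list of at least 50 UMIs, and Acod1 in every class. Igkc, and the genes set side by side within neutrophil-like cells of the combination, were chosen after their values were seen, and 1 to 4 of the members taken per list are printed. Of 30 gene lists, members with at least 20 UMIs were measured, with the number at least 1.5-fold higher or lower as a size only. List medians were set among 10000 random lists of the same size matched on mean expression in 20 bins. The lists of cytotoxic effector genes, T cell exhaustion and checkpoint genes, naive and memory T cell genes, T cell activation and regulatory T cell effector genes were to be read in T and NK cell classes alone, which were too small, so they were not analysed here. To compare shares of cells with a UMI, each cell was thinned to 1000 UMIs, which left out 980 shallower cells, 41 of vehicle, 32 of olaparib and 27 of combination neutrophil-like cells among them. Free RNA of macrophage-like genes was estimated at 3.20%, 3.77% and 3.73% of neutrophil-like UMIs in vehicle, olaparib and combination. Free RNA of neutrophil-like genes was estimated at 0.0693%, 0.0553% and 0.0422% of macrophage-like UMIs and at 0.420%, 0.572% and 0.0737% of cDC2-like UMIs. The latter estimates took all S100a8 and S100a9 RNA of the class as free. Identifiers and symbols came from the deposited feature tables, with 32285 genes, and positions from the GENCODE vM21 annotation of GRCm38, the build also called mm10, matched by Ensembl identifier, where 127 identifiers had no match.

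The alternatives fixed in advance were a stricter cell filter (500 genes, 1000 UMIs, 10% mitochondrial), no filter, the authors' cells, Leiden resolutions 0.5 and 2, each library clustered alone, TMM factors (edgeR), median-of-ratios factors and the mean over cells of each cell's scaled counts. Others were thinned cells, 5 pseudo-UMIs, 100 UMIs per list member, the mean over members and Acod1 after subtraction of free RNA. Some alternatives were added after seeing the data. They were removal of the 6% of cells with the highest doublet scores and pooling of the unnamed clusters 5, 14 and 20 into the macrophage-like class. The others were macrophage-like cells without cluster 9, equal weights of clusters in every library, and immune clusters as denominator of shares. The ratios and list percentiles were tested on simulated data drawn from the real class levels and totals, with 200 genes changed by known folds. In macrophage-like cells (combination to olaparib, 12732 genes) genes doubled in the simulation had a median log2 ratio of 1.0 and genes lowered 4-fold -2.03, with 96% of the latter within 0.5 of the true value. In neutrophil-like cells (3644 genes) the values were 0.96, -1.93 and 90%, and the direction was right for 100% of changed genes. The simulation held counting noise alone, with no variation between cells, clusters or tumours, and only genes with an expected 100 UMIs or more were changed. It cannot show how far such variation moves the ratios. Software was Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.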

Results

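Single-cell RNA was measured with droplet libraries (10x Genomics) in immune cells of BP mouse mammary tumours, which lack Brca1 and Trp53. The tumours came from mice given vehicle, olaparib, or olaparib together with IRG1-IN-1 (the combination). Olaparib inhibits PARP, an enzyme of DNA single-strand break repair. IRG1-IN-1 is a compound named for IRG1, the mitochondrial enzyme encoded by Acod1 that makes itaconate. Cells were released with digestive enzymes, enriched for the leukocyte surface protein CD45 and pooled from 4 tumours per treatment. Each treatment was 1 library, so there were no replicates, no test between treatments was possible, and treatment cannot be told apart from library or pool. All intervals are exact 95% intervals and cover counting error only. The deposited count matrices held 7787 barcodes with 149552244 UMIs for vehicle, 8857 with 208838169 for olaparib and 9488 with 167156207 for the combination. Median UMIs per barcode were 16670, 19778 and 14518, in that order. After the cell filter 7464, 8126 and 8563 cells were left.

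Macrophage-like cells, named by markers such as C1qa, Apoe and Adgre1, were the largest class of each library. Among named classes neutrophil-like cells, named by markers such as S100a8, S100a9 and Csf3r, came next in vehicle and olaparib. In the combination cDC2-like cells came next, at 6.68%, but only in the reported clustering. Under the other filters and clusterings cDC2-like cells were 0% to 4.26% of the combination and neutrophil-like cells 5.26% to 6.16%. Other named classes were type 2 and type 1 conventional dendritic cells (cDC2-like and cDC1-like), T and NK-like cells and, although CD45 had been selected, tumour epithelial-like and endothelial-like cells. The T and NK-like class leaves out unnamed clusters. In vehicle, olaparib and combination, the cluster nearest to CD4 T cells held 7, 7 and 14 cells and that nearest to CD8 T cells 7, 0 and 0. Other clusters led by T cell genes, with macrophage or cDC2 markers, held 14, 17 and 28 and 2, 5 and 11 cells. Share ratios with these cells were not computed. Clusters without a name held 28.7% (27.7 to 29.8) of vehicle, 31.8% (30.8 to 32.8) of olaparib and 35.1% (34.1 to 36.1) of combination cells. Clusters 5, 14 and 20, unnamed but nearest to macrophages by marker set, made up 9.89%, 9.45% and 12.7% of all kept cells in that order. The naming thresholds that kept them out were set after the data had been seen. Cluster 14 had 10 detected macrophage markers and was led by Cd209f and Ccl8, with Lyve1 and Cd163 among its top genes. Its MHC class II list summed to 188, 187 and 235 CPM, against 987, 1055 and 2737 CPM in macrophage-like cells. The macrophage-like class, and lists read in it that hold Lyve1 and Cd163, leave cluster 14 out. The macrophage-like class was made of different clusters in the 3 libraries. Cluster 0 (led by Ch25h, Ccl12 and Ccl7) and cluster 2 (Cd300a, Apoe and Selenop) held 28.2% and 21.4% of it in vehicle. Cluster 1 (Gdf15, Vcam1) and cluster 0 held 21.6% and 20.8% in olaparib. Clusters 1, 0 and 9 (Lyz1, Pde4c and Ifih1) held 20.6%, 18.0% and 17.2% in the combination, where cluster 9 had held 0.755% in vehicle and 5.40% in olaparib. Clusters 3, 12 and 15, led by histone and cell cycle genes, and cluster 7, led by Mmp12 and Arg1, held most of the rest. The neutrophil-like class was made of clusters 4 (led by S100a9 and S100a8) and 17 (Cxcl3 and Hcar2), both with Acod1 among their 10 leading genes. Cluster 4 held 701, 596 and 347 cells and cluster 17 held 204, 183 and 144 cells in vehicle, olaparib and combination. No alternative gave these clusters equal weights. CD45 selection, the mitochondrial filter and the depth gap between libraries can each set shares of cells: the filter removed 4.14% of vehicle, 8.25% of olaparib and 9.74% of combination barcodes.

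**Figure D1:**
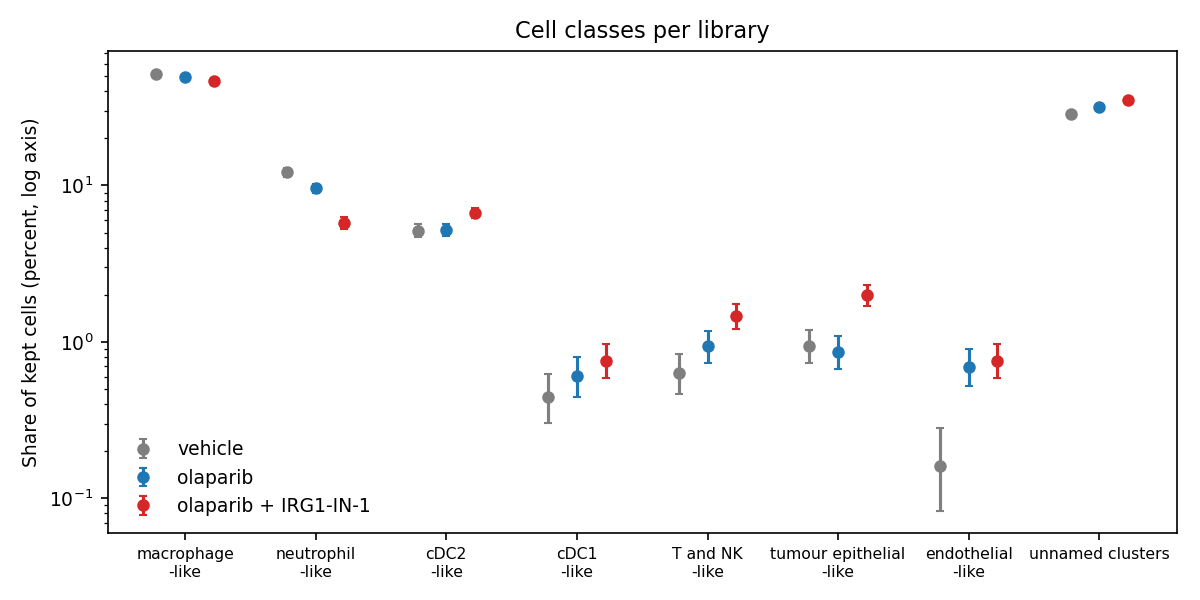
Share of kept cells in each cell class (log axis, percent) for the 3 libraries, 1 point per library with its exact 95% binomial interval. Neutrophil-like cells stood at 12.1%, 9.59% and 5.73% in vehicle, olaparib and combination, and T and NK-like cells at 0.630%, 0.935% and 1.46%.

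The comparison of olaparib with vehicle asked how the immune cells of these tumours differed under the PARP inhibitor alone. Macrophage-like cells of the olaparib library had more RNA for Ifih1, which encodes the cytosolic RNA sensor MDA5, at 122 against 36.4 CPM, a ratio of 3.35 (95% interval 3.22 to 3.49). They also had more Vcam1, an adhesion molecule, at 252 against 97.0 CPM (2.60-fold), and less of the inducible heat shock genes Hspa1a and Hspa1b and of Spp1, which encodes osteopontin. Neutrophil-like cells were 9.59% (8.95 to 10.2) of olaparib and 12.1% (11.4 to 12.9) of vehicle cells, a ratio of 0.791 (0.718 to 0.871), and had less of the granule gene Ngp, at 7.93 against 91.7 CPM. T and NK-like cells were 0.935% (0.738 to 1.17) of olaparib and 0.630% (0.463 to 0.836) of vehicle cells, 76 against 47 cells, a ratio of 1.49 (1.02 to 2.18). The unnamed T cell clusters are not in these counts, and with so few cells the ratio can depend on that naming.

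The macrophage-like share was 49.7% in olaparib and 51.5% in vehicle, a ratio of 0.965 (0.923 to 1.01), and the cDC2-like share was 5.21% and 5.14%. The cDC2-like shares were 1.92% and 1.79% under the stricter cell filter and 0.686% and 0.704% on the authors' cells, so their size depended on the processing. Treg-like cells numbered 28 against 10, with a share ratio of 2.57 (1.21 to 5.93), CD8 T-like cells 26 against 20, with 1.19 (0.641 to 2.26), and NK-like cells 19 against 12, with 1.45 (0.670 to 3.29). Endothelial-like cells, which CD45 selection should remove, numbered 56 against 12, with a share ratio of 4.29 (2.27 to 8.79). Median UMIs per cell of the macrophage-like class were 24734 in olaparib and 20007 in vehicle, and 2885 and 2081 in the neutrophil-like class.

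The 10 named genes that stood highest in olaparib macrophage-like cells were Ifih1 (ENSMUSG00000026896, chromosome 2, 62595798 to 62646255, GRCm38) and Vcam1 (ENSMUSG00000027962, chromosome 3, 116109949 to 116129688), followed by Tmcc3, Tmem176b, Ppp1r10, Mthfs, Kansl1l, Pde7b, Egr1 and Nr4a3. After the leading pair the ratios ran from 1.73 for Tmcc3 to 1.59 for Nr4a3. Egr1, an immediate early transcription factor, was at 336 against 209 CPM, Nr4a3, an orphan nuclear receptor, at 93.8 against 58.8 CPM, and Pde7b, a cyclic AMP phosphodiesterase, at 139 against 86.3 CPM. Egr1 is a member of the immediate early list, which was fixed as a list of tissue dissociation. Whether handling of the digested and frozen cells bears on Egr1 or on the heat shock genes was not tested. The 10 lowest were Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238), Hspa1a, Spp1, S100a4, Hsph1, Stk38l, Cd72, Adam8, Fabp5 and Olfm1. Hspa1b was at 98.5 against 192 CPM and Hspa1a at 196 against 366 CPM; the pair are near-identical copies, so the division of UMIs between them is uncertain. Spp1 was at 1316 against 2016 CPM, a ratio of 0.653 (95% interval 0.648 to 0.657), Fabp5, a fatty acid binding protein, at 473 against 631 CPM, and Adam8, a membrane metalloprotease, at 59.1 against 81.3 CPM. Vcam1 and Tmcc3 are also leading genes of cluster 1, Adam8 of cluster 7 and Ifih1 of cluster 9; without cluster 9 the Ifih1 log2 ratio was 1.55, against 1.74 with it.

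Among the gene lists, heat shock genes were lower in olaparib macrophage-like cells in 11 of 11 members, with a median log2 ratio of -0.28, and Hsph1, a co-chaperone, was at 61.0 against 84.7 CPM. In neutrophil-like cells the same list had a median of 0.29, with 4 of 11 members at least 1.5-fold higher in olaparib, among them Hsph1 at 21.3 against 7.47 CPM. Lipid-associated macrophage genes had a median of -0.18, with 9 of 14 members lower. NF-kappaB targets, at 0.22, and the interferon gamma response, at 0.22, had 12 of 14 and 11 of 15 members higher, with Birc3, an inhibitor of apoptosis, at 198 against 149 CPM and the chemokine gene Cxcl10 at 334 against 249 CPM. Type I interferon genes had a median of 0.17 and 23 of 26 members higher, 4 of them by at least 1.5-fold, such as Oasl1 at 21.5 against 10.5 CPM and Ifit1 at 6.43 against 3.75 CPM. Against 10000 random lists matched on expression, these 5 macrophage medians lay at percentiles 0, 0, 100, 99.9 and 100, as a description of these libraries.

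Other macrophage lists lay closer to 0. Medians were 0.16 for complement genes, 0.16 for cytokines and co-stimulation, 0.13 for alternatively activated and suppressive genes, 0.12 for p53 targets, -0.11 for NRF2 targets and the itaconate pathway and 0.091 for lysosomal genes. The alternatively activated list had a mean of -0.024, opposite in sign, because Retnla was at 0.181 against 1.83 CPM. They were -0.090 for proliferation genes, 0.069 for inflammasome genes, 0.065 for MHC class I presentation, 0.060 for the cGAS-STING pathway and 0.038 for the hypoxia response, and the last 3 turned negative under median-of-ratios scaling. Within the cGAS-STING list Ifnb1, the gene for interferon beta (ENSMUSG00000048806, chromosome 4, 88522025 to 88522774), was at 1.87 against 0.679 CPM. MHC class II presentation (-0.046), oxidative phosphorylation (-0.052), glycolysis (-0.041), unfolded protein response (0.028), immediate early genes (-0.018), myeloid chemokines (-0.015) and phagocytic receptors (0.00087) had medians within 0.1 of 0. Means over members had the opposite sign for MHC class II presentation, at 0.0051, and immediate early genes, at 0.059. The medians of proliferation and alternatively activated genes changed sign when each library was clustered alone, to 0.032 and -0.0071. With equal cluster weights those of glycolysis and oxidative phosphorylation did so too, to 0.015 and 0.012. Among chemokines, Cxcl3 was at 5.03 against 24.1 CPM, Ccl2 at 1736 against 2185 CPM and Ccl7 at 1704 against 2155 CPM.

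In neutrophil-like cells the 5 highest named genes in olaparib were Bcl2a1d, Bcl2a1b, Dars2, Cybb and Saa3, with ratios from 2.59 to 2.21. Bcl2a1b, an inhibitor of apoptosis whose UMIs may be shared with near-identical copies, was at 651 against 282 CPM, and Cybb, a subunit of the NADPH oxidase, at 75.1 against 33.9 CPM. The 5 lowest were Ngp, Cxcl10, Mmp8, Cd83 and P2rx7. Ngp (ENSMUSG00000032484, chromosome 9, 110419747 to 110423012) had 19 UMIs in olaparib and 184 in vehicle, a ratio of 0.0865 (95% interval 0.0509 to 0.139), and Mmp8, neutrophil collagenase, was at 47.6 against 109.6 CPM. The Cd83 log2 ratio of -1.13 was -0.14 once cells with the highest doublet scores were left out, and that of Ngp, -3.45, was -2.37 in thinned cells. Granule and immaturity genes had a median log2 ratio of -0.51 over 7 measured members, 3 at least 1.5-fold lower and 2 at least 1.5-fold higher in olaparib; Ly6g, a surface marker of neutrophils, was at 11.7 against 26.9 CPM and Ltf, lactoferrin, at 30.1 against 17.4 CPM. Type I interferon genes had a median of -0.10. The other neutrophil lists had medians of 0.23 (cytokines), 0.20 (unfolded protein response), 0.19 (inflammasome), 0.15 (tumour-associated neutrophil genes), 0.14 (NF-kappaB), 0.065 (hypoxia), 0.056 (immediate early), 0.048 (chemokines), 0.045 (p53), 0.028 (glycolysis), 0.019 (NRF2) and -0.060 (oxidative phosphorylation). The hypoxia median was -0.017 in thinned cells, and the means of the chemokine, p53 and glycolysis lists were -0.039, -0.042 and -0.031, opposite in sign to their medians.

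Acod1 (ENSMUSG00000022126, chromosome 14, 103046977 to 103056573) was mainly a transcript of neutrophil-like cells, which held 67.1% of its UMIs over all kept cells. Its level there was 2502 CPM in olaparib and 2413 CPM in vehicle, a ratio of 1.04 (0.998 to 1.08). In macrophage-like cells it was 9.31 and 10.7 CPM, a ratio of 0.869 (0.793 to 0.954), which was 1.22 when each library was clustered alone. In cDC2-like cells it was 35.7 against 8.92 CPM, a ratio of 4.0 (2.96 to 5.49), from 306 and 51 UMIs; 8.98% and 6.51% of cells had a UMI, and 3.07% and 1.30% of thinned cells. That ratio was 1.66 with finer clusters, from 20 UMIs in 3 olaparib cells and 7 UMIs in 5 vehicle cells. Subtraction of free neutrophil RNA left 21.4 CPM in olaparib and none in vehicle. The RNA counted as free was 0.420% and 0.572% of cDC2-like UMIs in vehicle and olaparib, against 0.0693% and 0.0553% in macrophage-like cells. Neutrophil RNA from doublets or misplaced cells was thus not told apart from free RNA. T and NK-like cells had 0 Acod1 UMIs in all 3 libraries, with upper interval ends of 10.5 CPM in vehicle, 6.23 in olaparib and 3.80 in the combination.

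**Figure D2:**
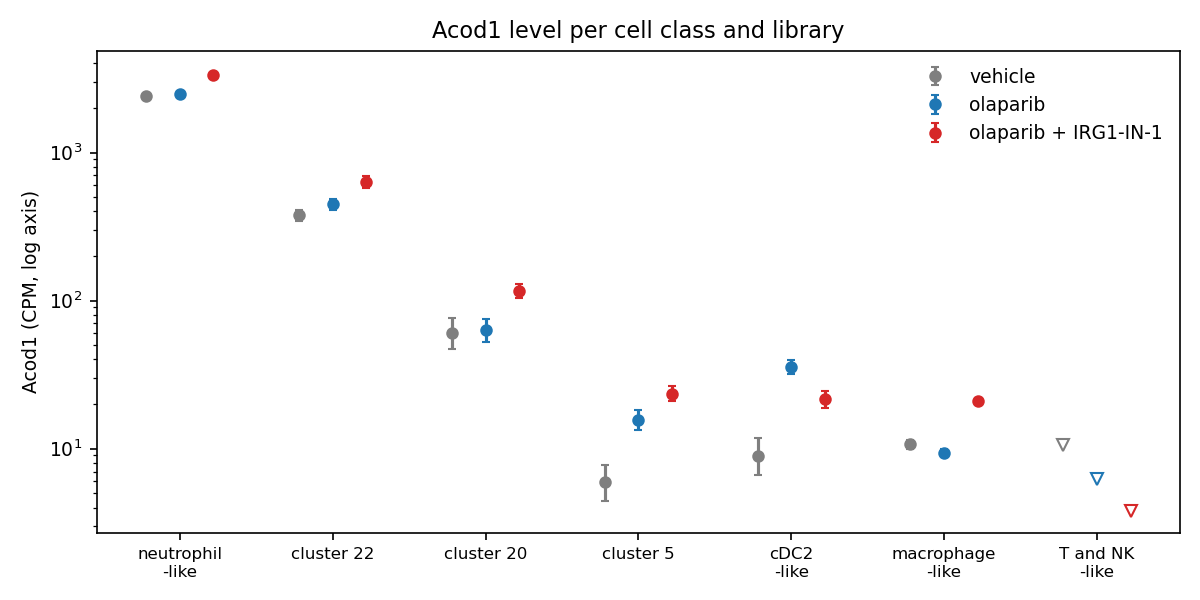
Acod1 level (CPM of summed UMIs, log axis) per cell class or cluster and library, with exact 95% Poisson intervals; open triangles mark the upper end of the interval where no UMI was seen. Neutrophil-like cells stood at 2413, 2502 and 3359 CPM and macrophage-like cells at 10.7, 9.31 and 20.9 CPM in vehicle, olaparib and combination.

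The comparison of the combination with olaparib asked what differed when IRG1-IN-1 was given on top of the PARP inhibitor. Neutrophil-like cells of the combination library had higher levels of all 24 measured type I interferon genes, each by at least 1.5-fold, with a median log2 ratio of 3.92 (15.1-fold) at percentile 100 of random lists. Macrophage-like cells had higher MHC class II presentation genes, with a median log2 ratio of 1.37 (2.58-fold), and higher type I interferon genes, with a median of 0.56 (1.48-fold). Neutrophil-like cells were 5.73% (5.25 to 6.25) of the combination cells against 9.59% (8.95 to 10.2) in olaparib, a ratio of 0.598 (0.533 to 0.671), and T and NK-like cells were 1.46% (1.22 to 1.74) against 0.935% (0.738 to 1.17), a ratio of 1.56 (1.16 to 2.10). Acod1 was higher by 1.34-fold in neutrophil-like and 2.25-fold in macrophage-like cells; in the former the cells rich in interferon RNA carried the difference, and in cDC2-like cells the direction depended on the processing.

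The interferon genes were the 5 highest named genes of neutrophil-like cells. Rsad2, which encodes the antiviral protein viperin (ENSMUSG00000020641, chromosome 12, 26442746 to 26456452), was at 1429.9 CPM in the combination and 7.51 CPM in olaparib, from 1783 and 18 UMIs, a ratio of 190.3 (95% interval 120.0 to 322). Ifit2 (ENSMUSG00000045932, chromosome 19, 34550694 to 34576419) was at 641 against 4.17 CPM, Ifit3 at 411 against 2.92 CPM and Ifit1 at 476 against 5.84 CPM; these genes encode interferon-induced RNA-binding or adaptor proteins. Ifit3b, a near-identical copy of Ifit3 that may share its UMIs, had 245 UMIs against 1, a ratio of 471 (95% interval 83.7 to 18664). In cells thinned to 1000 UMIs the log2 ratios of Rsad2 and Ifit1, 7.47 and 6.22, were 6.39 and 4.88, and those of Ifit3 and Ifit3b, 6.90 and 7.70, were 5.46 and 6.84. The Ifit2 log2 ratio, 7.09, was 6.24 as a mean over cells, and with 5 pseudo-UMIs that of Ifit3b was 6.02. A minority of cells carried most of this RNA: of 464 thinned combination cells 67, or 14.4% (11.4 to 18.0), had 10 or more UMIs of the list, against 0.937% (0.378 to 1.92) in olaparib and 0.810% (0.326 to 1.66) in vehicle. The median cell had 1 such UMI in the combination and 0 in olaparib, and 14 combination cells lay between 8 and 12 UMIs. Rsad2 was detected in 13.6% of these thinned cells and 16.1% of the unthinned ones, against 0.937% and 1.16% in olaparib; in macrophage-like cells of the combination, with a median of 18141 UMIs against 2384, the thinned share was 1.45%. In NK-like cells of the combination 0 of 27 thinned cells had an Rsad2 UMI, with an upper interval end of 12.8% and a median depth of 11052 UMIs. Monocyte markers summed to 1198 CPM in combination and 846 CPM in olaparib neutrophil-like cells, and macrophage markers to 1009 and 1149.7 CPM.

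**Figure D3:**
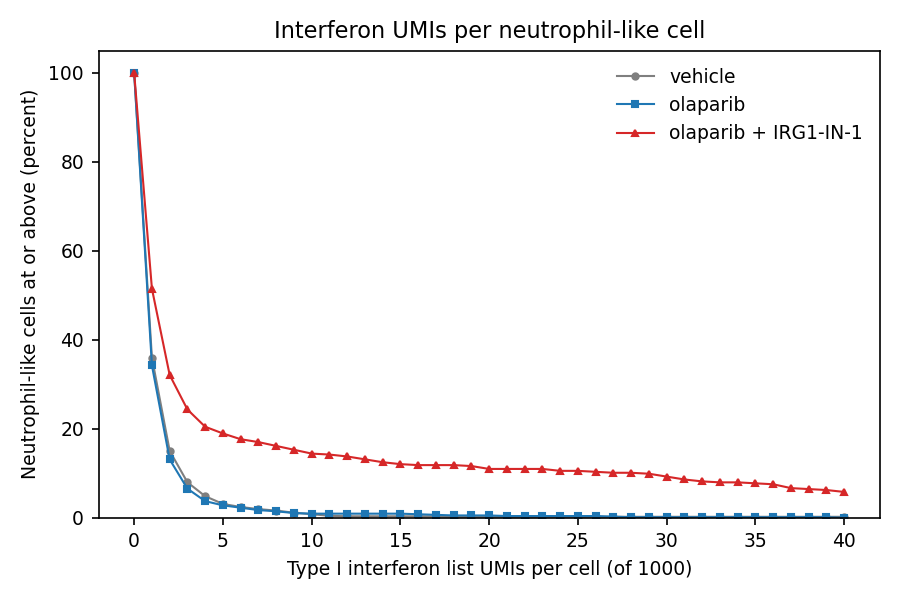
Percentage of neutrophil-like cells (y axis) with at least the number of type I interferon list UMIs on the x axis, each cell thinned to 1000 UMIs, 1 line per library. At 10 UMIs the combination stood at 14.4%, olaparib at 0.937% and vehicle at 0.810%.

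The median gene of neutrophil-like cells had a log2 ratio of -0.12 between these libraries and -0.14 between combination and vehicle, so list medians are to be read against those values; the median macrophage gene was within 0.05 of 0 in each comparison. Granule and immaturity genes had a median of 1.18, with 4 of 7 members at least 1.5-fold higher, 1 at least 1.5-fold lower and 3 below 0 in all: Ngp was at 89.8 against 7.93 CPM, Ly6g at 74.6 against 11.7 CPM and Lcn2, lipocalin 2, at 686 against 302 CPM. Vehicle had Ngp at 91.7 CPM, so for this gene the combination was close to vehicle and olaparib was low. Chemokine genes had a median of 0.30; Ccl4, a ligand of CCR5, was at 5016 against 1648 CPM, and Ccl5 had 80 UMIs against 1. Heat shock genes, with a median of -0.45, were lower in 10 of 11 members, such as Hspa1a at 68.2 against 137 CPM, and immediate early genes, at -0.28, in 11 of 13, such as Egr1 at 1738 against 2391 CPM. Percentiles of these 4 medians among random lists were 100, 99.9, 0.060 and 0.0450. Hypoxia genes had a median of -0.27, with Vegfa, an angiogenic growth factor, at 148 against 245 CPM. The remaining medians lay between -0.16 for glycolysis and 0.20 for cytokines and co-stimulation, where Il1a was at 415 against 248 CPM and Ptgs2 at 1944 against 2827 CPM. The 5 lowest named genes were Txnl4a, Usp37, Slc41a1, Col6a3 and Atp5g2, with ratios from 0.437 to 0.469; Usp37, a deubiquitinase, was at 74.6 against 162 CPM, and Atp5g2, an ATP synthase subunit, at 32.9 against 70.1 CPM. The Col6a3 log2 ratio of -1.09 was -1.74 in thinned cells.

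In macrophage-like cells the highest named genes were Lyz1, H2-Ab1, H2-Aa, F10, Oasl1, Cd74, Ifih1, Plxdc2, Ifitm3 and Mmp12. Lyz1, a lysozyme gene (ENSMUSG00000069515, chromosome 10, 117287797 to 117292868), was at 214 against 27.1 CPM, a ratio of 7.90 (95% interval 7.59 to 8.22); UMIs may be shared with its paralog Lyz2, and Lyz1 leads cluster 9, without which its log2 ratio of 2.98 was 2.13. The MHC class II chain genes H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823) and H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34257689 to 34269419) were at 612 against 193 CPM and 361 against 111 CPM, and Cd74, the invariant chain of MHC class II (ENSMUSG00000024610, chromosome 18, 60803848 to 60812652), at 1560.2 against 605 CPM, a ratio of 2.58 (95% interval 2.56 to 2.61). Ifih1 was at 313 against 122 CPM, F10, coagulation factor X, at 51.8 against 16.7 CPM, Ifitm3, an interferon-induced restriction factor of virus entry, at 510.1 against 222 CPM, and Mmp12, macrophage elastase, at 253 against 119 CPM. Mmp12 is also a leading gene of cluster 7, and its log2 ratio of 1.09 was 2.88 when each library was clustered alone. The 10 lowest were Fcrls, Nxpe5, Npl, Paox, Cela1, Gstp1, Tspan4, Scoc, Tmem86a and Cxcr4, with ratios from 0.606 to 0.717. Fcrls, an Fc receptor-like gene, was at 525 against 867 CPM, Npl, an enzyme of sialic acid breakdown, at 443 against 678 CPM, Gstp1, a glutathione S-transferase, at 36.0 against 51.6 CPM, and Cxcr4, the receptor of Cxcl12, at 128 against 178 CPM. Fcrls and Npl are also leading genes of cluster 0 and Cxcr4 of cluster 2. H2-Ab1, H2-Aa, Cd74 and F10 are also leading genes of cluster 6, the cDC2-like cluster, whose share of cells depended on the processing.

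By list, MHC class II presentation had 6 of 9 members at least 1.5-fold higher, among them the transactivator gene Ciita at 4.76 against 1.48 CPM and H2-Eb1 at 12.1 against 3.39 CPM, and its summed level was 2737 against 1055 CPM. Marker genes of cDC2 in the same cells summed to 138 and 94.9 CPM, and those of monocytes to 3042 and 2637 CPM. Type I interferon genes were higher in 26 of 26 members, 12 by at least 1.5-fold, with Irf7, an interferon regulatory factor, at 39.6 against 15.4 CPM; the median of 0.56 was 0.12 when each library was clustered alone. Myeloid chemokines had a median of 0.31, with Ccl5 at 18.7 against 8.38 CPM and Ccl24 at 22.4 against 9.47 CPM, and the interferon gamma response 0.24, with Cd274, the gene for PD-L1, at 51.7 against 36.5 CPM. The interferon gamma median was -0.11 when each library was clustered alone. Unfolded protein response genes had a median of 0.22, heat shock genes 0.20 and NF-kappaB targets 0.16. Percentiles of these 7 medians were 100, 100, 100, 100, 100, 100 and 100, in the order given. Cytokine and co-stimulation genes had a median of 0.073 and 5 of 15 members at least 1.5-fold higher, such as Cd40 at 35.7 against 20.9 CPM and Il23a at 19.9 against 8.48 CPM. Medians of the remaining lists ranged from -0.089 for lysosomal genes to 0.11 for MHC class I presentation, with NRF2 targets and the itaconate pathway at 0.039. The alternatively activated list had a median of -0.020 and a mean of 0.44, with Retnla at 3.08 against 0.181 CPM; phagocytic receptors, glycolysis and immediate early genes also had means opposite in sign to their medians, all within 0.05 of 0. The hypoxia median was 0.047, and 0.71 with each library clustered alone, where that of glycolysis, -0.028, was 0.26. Ifnb1 was at 5.55 against 1.87 CPM.

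Acod1 was at 3359 CPM in neutrophil-like cells of the combination and 2502 CPM in olaparib, a ratio of 1.34 (1.29 to 1.40), and at 20.9 and 9.31 CPM in macrophage-like cells, a ratio of 2.25 (2.08 to 2.44). In neutrophil-like cells with fewer than 10 interferon UMIs of 1000 it was 2515 CPM in the combination and 2504 CPM in olaparib, against 7040.1 CPM in the 67 combination cells at or above that threshold, so these cells carried the difference of the class; the split rests on a level measured in the same cells. In cDC2-like cells it was at 21.5 against 35.7 CPM, a ratio of 0.604 (0.504 to 0.723). That ratio was 2.15 under the stricter filter and 1.90 with finer clusters, each with 20 olaparib UMIs in 3 cells. It was 0.893 after subtraction of free RNA, so no direction is read. Of the cDC2-like cells in the reported clustering 9.62% and 8.98% had a UMI before thinning and 2.27% and 3.07% after it. In thinned cells an Acod1 UMI was seen in 58.4% of neutrophil-like cells of the combination and 50.1% of those of olaparib, 64.4% and 58.2% before thinning. In macrophage-like cells the thinned shares were 1.5% and 0.693% (6.89% and 4.48% before thinning), while 0 of 64 and 0 of 49 thinned cDC1-like cells, with median depths of 18299 and 22787 UMIs, had any (upper interval ends 5.60% and 7.25%); before thinning the shares were 4.62% and 0%, from 5 and 0 UMIs. The mRNA level does not measure the enzyme that the compound is named for.

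The macrophage-like share was 46.6% in the combination and 49.7% in olaparib, a ratio of 0.938 (0.898 to 0.980), but 1.02 with each library clustered alone. The cDC2-like ratio was 1.28 (1.13 to 1.46), and 1.84 under the stricter cell filter and 3.09 with each library clustered alone, so its size depended on the processing. Mature DC-like cells numbered 23 against 6, with a share ratio of 3.64 (1.44 to 10.9), and plasmacytoid DC-like cells 21 against 7, with 2.85 (1.17 to 7.93). Treg-like cells numbered 47 against 28, with a share ratio of 1.59 (0.977 to 2.64), and CD8 T-like cells 41 against 26, with 1.5 (0.894 to 2.55); both intervals include 1. Tumour epithelial-like cells, outside the CD45 gate, were 1.99% against 0.861%, a ratio of 2.30 (1.73 to 3.09). No T cell class reached 100 cells in each library, so gene ratios and list medians within T cell classes were not compared. Summed interferon list levels of Treg-like cells are given further below as values only.

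The comparison of the combination with vehicle asked how both compounds together differed from no drug; it shares a library with each of the other comparisons and is not independent of them. Type I interferon genes were higher in 26 of 26 members in macrophage-like cells, with a median log2 ratio of 0.89 (1.86-fold) that was 0.36 when each library was clustered alone, and in all 24 measured members in neutrophil-like cells, with a median of 3.69 (12.9-fold). The MHC class II list had a median of 1.54 in macrophage-like cells (2.91-fold), which was 0.71 when each cluster had the same weight in every library. Neutrophil-like cells were 5.73% against 12.1% of cells, a ratio of 0.473 (0.423 to 0.528). T and NK-like cells were 1.46% against 0.630%, a ratio of 2.32 (1.65 to 3.32), which was 1.25 when each library was clustered alone.

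The 10 highest named genes in macrophage-like cells were Lyz1, Ifih1, Oasl1, F10, Plxdc2, H2-Aa, H2-Ab1, Cd74, Tmem176a and Axl. Ifih1 was at 313 against 36.4 CPM, a ratio of 8.59 (95% interval 8.27 to 8.93), Oasl1, an interferon-induced member of the OAS family, at 65.3 against 10.5 CPM, and Axl, a receptor for Gas6 that takes part in uptake of dead cells, at 80.3 against 30.5 CPM. Log2 ratios of 3.15 for Lyz1 and 2.29 for F10 were 2.25 and 1.63 without cluster 9, and that of Oasl1, 2.64, was 1.73 with each library clustered alone. The log2 ratio of Plxdc2, 1.90, was 1.23 with equal cluster weights, and those of H2-Aa and H2-Ab1, 1.73 and 1.66, were 2.40 and 2.26 with finer clusters. The 10 lowest were Rapsn, Fcrls, Gstp1, Stk38l, Ccl7, Hist1h1e, Npl, Hist1h2ae, Ccl2 and Paox. The monocyte-attracting chemokine genes Ccl2 and Ccl7 were at 1458 against 2185 CPM and 1388 against 2155 CPM, ratios of 0.667 and 0.644, and Fcrls was at 525 against 836 CPM; Ccl7, Fcrls, Npl and Ccl2 are all among the 10 leading genes of cluster 0, whose part of the class was smaller in the combination. The histone genes Hist1h1e and Hist1h2ae, whose UMIs can be shared with near-identical copies, were at 167 against 258 CPM and 101 against 152 CPM.

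Macrophage lists with medians above 0.25 were, besides these, cytokines and co-stimulation at 0.48, the interferon gamma response at 0.40, myeloid chemokines at 0.31, NF-kappaB targets at 0.28 and alternatively activated and suppressive genes at 0.28. The last of these was -0.21 when each library was clustered alone. Il23a was at 19.9 against 5.92 CPM, Cd40 at 35.7 against 13.4 CPM, Il12b at 1.20 against 3.71 CPM, Cxcl10 at 455 against 249 CPM and Arg1, arginase 1, at 496 against 268 CPM. Ifnb1 was at 5.55 against 0.679 CPM, a log2 ratio of 3.01. The lowest medians were -0.16 for heat shock genes, -0.13 for phagocytic receptors, whose mean was 0.22, -0.12 for proliferation genes and -0.11 for oxidative phosphorylation, where 21 of 25 members were lower. The remaining medians ranged from -0.057 for glycolysis to 0.20 for complement, with NRF2 targets and the itaconate pathway at 0.0052. The hypoxia median was 0.11, and 0.76 with each library clustered alone. With equal cluster weights the proliferation and immediate early medians, -0.12 and 0.089, were 0.025 and -0.12.

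In neutrophil-like cells Ifit2 had 799 UMIs in the combination and 1 in vehicle, a ratio of 1286 (95% interval 230.2 to 50859), and Rsad2 was at 1429.9 against 18.4 CPM; Ifit3b, Ifit3 and Ifit1 were the other 3 of the 5 highest named genes. In thinned cells the log2 ratios of Ifit2, Ifit3b and Ifit3, 9.28, 7.58 and 5.88, were 7.60, 5.99 and 4.97, and the median of the type I interferon list was 2.95. The 5 lowest were Cd83, Mt1, Fbxl20, P2rx7 and Mrps15; Mt1, a metallothionein, was at 38.5 against 88.7 CPM and P2rx7, an ATP-gated ion channel, at 45.7 against 91.2 CPM. Without the cells of highest doublet scores the log2 ratios of Cd83 and Mt1, -1.38 and -1.19, were -0.21 and -0.54. Granule and immaturity genes had a median of 0.67, inflammasome genes 0.38, NF-kappaB targets 0.33 and chemokines 0.31, with Ccl4 at 5016 against 1243 CPM. Of the granule and immaturity genes 6 of 7 were higher, while Ngp was at 89.8 against 91.7 CPM. The remaining medians ranged from -0.26 for oxidative phosphorylation to 0.25 for the unfolded protein response. Acod1 ratios were 1.39 (1.34 to 1.45) in neutrophil-like cells, 1.95 (1.80 to 2.12) in macrophage-like cells and 2.42 (1.77 to 3.35) in cDC2-like cells. The cDC2-like ratio was 1.47 as a mean over cells. Under the stricter filter it was 4.24, from 70 UMIs in 17 combination cells and 7 UMIs in 5 vehicle cells. In neutrophil-like cells with fewer than 10 interferon UMIs the Acod1 levels were 2515 and 2374 CPM. The share ratios were 0.905 (0.866 to 0.947) for macrophage-like and 1.30 (1.14 to 1.48) for cDC2-like cells (1.97 under the stricter filter and 1.93 with finer clusters). They were 4.10 (2.04 to 9.09) for Treg-like and 1.79 (1.02 to 3.22) for CD8 T-like cells. The CD8 T-like ratio, from 41 and 20 cells, leaves out the unnamed cluster nearest to CD8 T cells, with 0 combination and 7 vehicle cells. Mature DC-like cells numbered 23 against 2 and endothelial-like cells 65 against 12.

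**Figure D4:**
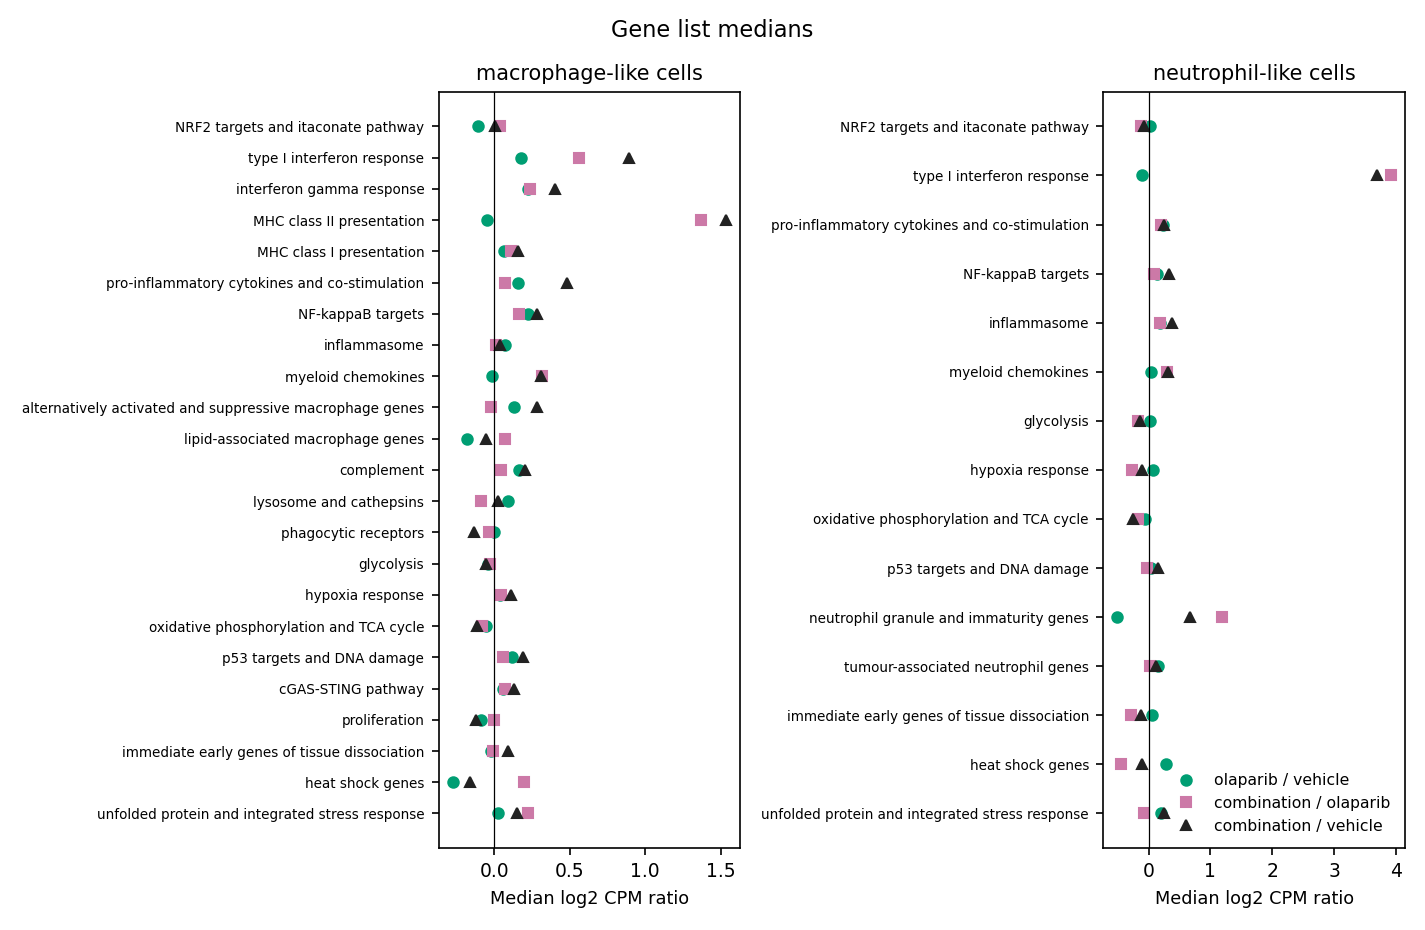
Median log2 CPM ratio of the measured members of each gene list in macrophage-like (left) and neutrophil-like cells (right), 1 symbol per comparison, with the vertical line at no difference; the x axes differ in range. The type I interferon list stood at 3.92 and 3.69 in neutrophil-like cells for combination over olaparib and over vehicle, and MHC class II presentation at 1.37 and 1.54 in macrophage-like cells.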

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

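These values come from cells that no comparison used, or from a gene kept out of the named genes, and in at least 1 treated library stood above vehicle with exact 95% intervals that did not overlap. Values below vehicle were not sought by this rule. Clusters 11 and 16, nearest to fibroblasts by marker set, were 4.38% and 3.03% of vehicle cells and 2.20% and 1.49% of combination cells. Cluster 22 was 1.10% of vehicle and 0.444% of combination cells. The test of free RNA from plasma cells was chosen after the result had been seen, and that of a few cells before. Cluster 5, led by Ccr2, Fgf13 and Spp1, was 7.94% (7.38 to 8.53) of combination cells and 6.28% (5.74 to 6.86) of vehicle cells, but lower in olaparib, at 5.32% (4.84 to 5.83). Cluster 8, shallow cells with a median of 1178 UMIs led by the mast cell genes Tpsab1 and Mcpt4 and the platelet gene Ppbp, was 6.14% of olaparib, 6.04% of combination and 3.97% of vehicle cells. Cluster 10, led by Lrmda and Zdhhc14 and with a median mitochondrial share of 5.84%, was 5.37% of combination, 2.84% of olaparib and 3.26% of vehicle cells. Cluster 13, led by the fat cell genes Cfd and Car3, was 3.99% of olaparib, 2.37% of combination and 2.44% of vehicle cells. Cluster 18, led by Rorb, Cdh2 and Krt8, was nearest to tumour epithelial cells by marker set. It was 1.10% (0.880 to 1.35) of olaparib and 3.77% (3.38 to 4.20) of combination cells against 0.174% (0.0928 to 0.298) of vehicle. Its median UMIs were 57211, and CD45 selection can set its share. Cluster 20, led by Ifit2, Rsad2 and Ly6c2, was 2.13% (1.83 to 2.45) of combination, 1.22% of olaparib and 0.857% (0.661 to 1.09) of vehicle cells. Barcodes removed for a mitochondrial share over 15% were 8.25% of olaparib and 9.74% of combination barcodes against 4.14% of vehicle.

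Igkc, the constant region of the immunoglobulin kappa light chain (ENSMUSG00000076609, chromosome 6, 70726435 to 70726966), was at 59.6 CPM in macrophage-like cells of the combination and 0.0494 CPM in vehicle, with 0 UMIs in olaparib. Free RNA from plasma cells reaches all droplets of a library alike, but neutrophil-like cells carried 2.69% of that level, which argues against it. The 10 cells with the most Igkc held 99.4% of the UMIs, and 1 cell alone held 4555 of 4628, so the level rests on a few cells. Marker genes of plasma cells summed to 16554 CPM in that cell and those of macrophages to 249.7 CPM, consistent with a plasma cell placed in a macrophage-like cluster; this was looked at after the result was known. Whether the treatment bears on the presence of that cell cannot be read from 1 cell.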

How the results depend on the processing

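Of 86 alternative values of the share ratios 67 lay within the counting interval of the reported value, 17 lay outside it without a reversal and 2 reversed, where a reversal is a change of sign of a value whose interval excluded no difference. For the Acod1 ratios the numbers were 62, 33 and 5 of 100, and for the type I interferon and MHC class II medians 72, 63 and 0 of 135. Of the values outside the interval 1, 0 and 8, in that order, had the other sign, where the reported interval included no difference: between olaparib and vehicle, 1 of the macrophage-like share ratio, 1 of the neutrophil-like type I interferon median and the rest of the macrophage-like MHC class II median, for which no direction is read. Of 1260 alternative values of named genes 0 reversed, and of 1553 of the other lists 30, in 19 list medians, given below. A further 506 and 405 lay outside their interval and are not listed. Named genes were picked for the most extreme ratios in the same counts. A reversal was therefore unlikely from the start, and its absence is no sign of robustness. The neutrophil-like share ratios ranged from 0.762 to 0.835, 0.585 to 0.608 and 0.450 to 0.507 over the alternatives. The answers that reversed in this sense were the macrophage-like share ratio between combination and olaparib and the macrophage-like Acod1 ratio between olaparib and vehicle, both close to 1, and the cDC2-like Acod1 ratio between combination and olaparib. The cDC2-like reversals, under the stricter filter and with finer clusters, each rest on 20 olaparib UMIs in 3 cells. The counts of alternative values cover macrophage-like, neutrophil-like and cDC2-like cells, with T and NK-like cells for shares. Ratios of the other classes were not tried. No cDC2-like cluster was named without a cell filter, at Leiden resolution 0.5 or in the vehicle library clustered alone, and such cells of vehicle and olaparib held 0 Acod1 UMIs without the highest doublet scores and 0 on the authors' cells, nor did olaparib clustered alone hold any, so the ratios that need them have no value. Free RNA subtraction left no Acod1 in vehicle cDC2-like cells. No T and NK-like cluster was named at Leiden resolution 0.5, nor in the olaparib library clustered alone, so those ratios have no value there. Cluster names also moved: under several alternatives 7.44% or more of vehicle cells were named monocyte-like, where the reported clustering named none. Scrublet removed no cell, so keeping doublets was the reported setting itself. No paired analysis was possible because each group was 1 library. Depth of single cells was also looked at as a source of the neutrophil interferon medians, which in thinned cells were 3.71 over olaparib and 2.95 over vehicle, against 3.92 and 3.69 as reported. Depth limits the neutrophil-like values most, with 1246967 UMIs in the combination against 77595468 in macrophage-like cells.

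Of the share, Acod1, type I interferon and MHC class II answers the values outside their interval follow, and of the other lists the reversed ones. The first comparison is olaparib to vehicle, the second combination to olaparib and the third combination to vehicle, medians are log2 ratios of gene lists, and the cause of each difference was not tested. Under the stricter cell filter, the macrophage share ratio was 0.970 in the third, the cDC2 share ratio was 1.84 in the second and 1.97 in the third, and the macrophage MHC class II median was 0.18 in the first and 1.22 in the second. The macrophage type I interferon median was 0.53 in the second and 0.79 in the third, the macrophage lipid-associated median was -0.017 in the second, and the cDC2 Acod1 ratio was 1.98 in the first, 2.15 in the second and 4.24 in the third. With no cell filter, the macrophage share ratio was 0.911 in the first, 0.845 in the second and 0.770 in the third, the macrophage MHC class II median was 0.083 in the first, 1.05 in the second and 1.14 in the third, and the macrophage Acod1 ratio was 1.98 in the second. The macrophage type I interferon median was 0.50 in the second and 0.77 in the third. At Leiden resolution 0.5, the macrophage type I interferon median was 0.24 in the first, 0.47 in the second and 0.77 in the third, the macrophage Acod1 ratio was 1.81 in the second and 1.52 in the third, and the macrophage MHC class II median was 1.32 in the second and 1.56 in the third. At Leiden resolution 2, the cDC2 share ratio was 1.19 in the first, 1.62 in the second and 1.93 in the third, the macrophage MHC class II median was 0.27 in the first, 1.45 in the second and 1.95 in the third, and the cDC2 Acod1 ratio was 1.66 in the first and 1.90 in the second. When each library was clustered alone, the macrophage share ratio was 0.887 in the first and 1.02 in the second, the T and NK share ratio was 1.25 in the third, and the cDC2 share ratio was 3.09 in the second. The macrophage Acod1 ratio was 1.22 in the first, 2.07 in the second and 2.53 in the third, the macrophage MHC class II median was 0.19 in the first, 1.45 in the second and 1.68 in the third, and the macrophage alternatively activated median was -0.0071 in the first and -0.21 in the third. The macrophage proliferation median was 0.032 in the first, the macrophage type I interferon median was 0.12 in the second and 0.36 in the third, and the macrophage interferon gamma median was -0.11 in the second. The macrophage glycolysis median was 0.26 in the second and 0.16 in the third, and the macrophage lipid-associated median was 0.22 in the third. On the cells of the authors' normalised matrix, the cDC2 share ratio was 1.51 in the second, the macrophage Acod1 ratio was 0.737 in the first, 2.90 in the second and 2.14 in the third, and the macrophage MHC class II median was 0.22 in the first and 1.28 in the second. With TMM factors, the macrophage MHC class II median was -0.10 in the first and 1.35 in the second, the macrophage hypoxia median was -0.018 in the first, and the macrophage lysosome median was -0.049 in the third. The neutrophil Acod1 ratio was 1.43 in the second and 1.5 in the third. With median-of-ratios factors, the macrophage type I interferon median was 0.11 in the first, the macrophage MHC class II median was -0.11 in the first, and the macrophage MHC class I median was -0.0025 in the first. The macrophage hypoxia median was -0.030 in the first, the macrophage cGAS-STING pathway median was -0.0083 in the first, and the macrophage lysosome median was -0.053 in the third. The neutrophil Acod1 ratio was 1.44 in the second and 1.5 in the third. As a mean over cells, the macrophage Acod1 ratio was 0.787 in the first, the macrophage type I interferon median was 0.11 in the first and 0.79 in the third, and the macrophage MHC class II median was 0.074 in the first, 1.26 in the second and 1.61 in the third. The neutrophil Acod1 ratio was 1.27 in the second and 1.32 in the third, the neutrophil type I interferon median was 3.51 in the second, and the cDC2 Acod1 ratio was 2.39 in the first and 1.47 in the third. In cells thinned to 1000 UMIs, the macrophage Acod1 ratio was 1.04 in the first and 2.41 in the third, the macrophage type I interferon median was 0.73 in the second and 0.95 in the third, and the macrophage MHC class II median was 1.49 in the second and 1.71 in the third. The macrophage lysosome median was -0.0026 in the third, the neutrophil type I interferon median was 0.064 in the first and 2.95 in the third, and the neutrophil hypoxia median was -0.017 in the first. The neutrophil Acod1 ratio was 1.28 in the second and 1.32 in the third, and the cDC2 Acod1 ratio was 2.72 in the first and 1.53 in the third. As a mean over list members, the macrophage type I interferon mean was 0.26 in the first, 0.74 in the second and 1.0 in the third, the macrophage alternatively activated mean was -0.024 in the first, and the macrophage MHC class II mean was 0.98 in the second and 0.99 in the third. The macrophage phagocytic receptors mean was 0.029 in the second and 0.22 in the third, the macrophage glycolysis mean was 0.027 in the second, and the macrophage lipid-associated mean was 0.0036 in the third. With 100 UMIs required per list member, the neutrophil type I interferon median was 4.44 in the second and 4.28 in the third. After subtraction of free RNA, the macrophage Acod1 ratio was 2.46 in the second and 2.16 in the third, and the cDC2 Acod1 ratio was 0.893 in the second.

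The remaining alternatives were chosen after seeing the data. With the highest doublet scores removed, the cDC2 share ratio was 1.5 in the third, the macrophage MHC class II median was 0.24 in the first, 1.34 in the second and 1.64 in the third, and the macrophage Acod1 ratio was 2.49 in the second. With the unnamed clusters 5, 14 and 20 pooled into the macrophage-like class, the macrophage Acod1 ratio was 1.05 in the first and 2.21 in the third. The macrophage MHC class II median was 1.16 in the second and 1.32 in the third, and the macrophage type I interferon median was 0.69 in the third. The macrophage share ratio was 1.0 in the second and 0.966 in the third. Without cluster 9, the macrophage MHC class II median was -0.19 in the first, 1.14 in the second and 1.12 in the third, the macrophage Acod1 ratio was 2.04 in the second and 1.76 in the third, and the macrophage type I interferon median was 0.50 in the second and 0.78 in the third. The macrophage glycolysis median was 0.010 in the second, and the macrophage proliferation median was 0.047 in the third. With equal cluster weights, the macrophage MHC class II median was -0.084 in the first, 0.98 in the second and 0.71 in the third, the macrophage glycolysis median was 0.015 in the first and 0.044 in the third, and the macrophage oxidative phosphorylation median was 0.012 in the first. The macrophage proliferation median was 0.067 in the first and 0.025 in the third, the macrophage Acod1 ratio was 1.97 in the second, and the macrophage type I interferon median was 0.49 in the second and 0.74 in the third. The macrophage lipid-associated median was 0.0010 in the third, and the macrophage immediate early median was -0.12 in the third. With immune clusters as denominator, the macrophage share ratio was 1.02 in the first and 0.971 in the third.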

Other observations

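All tests below except that of doublets with macrophages were chosen after the result had been seen. Interferon and antigen presentation genes also differed between libraries in cell classes not described so far. In cDC2-like cells the type I interferon list summed to 581 CPM in vehicle, 780.5 in olaparib and 986 in the combination, and the MHC class II list to 14978, 17731 and 21217 CPM. In cDC1-like cells, with 33, 49 and 65 cells, the MHC class II list summed to 36840, 35989 and 33456 CPM and was lowest in the combination. The top genes of cluster 20 by fold include Ifit2 and Rsad2, although members of the type I interferon list were kept out of the clustering. Its levels of that list were 11978 CPM in vehicle, 11582 in olaparib and 10216 in the combination, so cells rich in this RNA were present without either compound. Clusters 11 and 16, led by Postn, a matrix protein gene of stromal cells, and by Prl2c3, stood at 459, 537 and 753 CPM and at 231, 295 and 382 CPM of the interferon list. Other classes differed otherwise: tumour epithelial-like cells stood at 347, 234 and 254 CPM, cluster 18 at 399.8, 739.5 and 484 CPM and Treg-like cells, with 10, 28 and 47 cells, at 3337, 1476 and 1302 CPM, while fibroblast-like cells had 1571 in olaparib and 1309 CPM in the combination.

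The 67 neutrophil-like cells of the combination with 10 or more interferon UMIs of 1000 were set apart by a threshold on a range of values, and whether they are a separate state was not tested. Their summed Acod1 was 7040.1 CPM against 2515 CPM in the 397 cells below 10, Ccl4 was 15771 against 2625, Ly6g 231 against 38.1 and Mmp8 327 against 149 CPM, while Ngp was 61.0 against 96.2. As medians over cells, neutrophil markers were 66113 against 23579.6 CPM, monocyte markers 1333 against 473 and macrophage markers 702 against 822 CPM. These cells had a median of 3409 UMIs and the others 2346, and the groups were made by a level measured in them, so no order of events follows.

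For the type I interferon genes of neutrophil-like cells in the combination, free RNA was weighed first: it mirrors the mixture of all other kept cells, but the list stood 7.32-fold above that mixture, which argues against it. An earlier form of this test, against the cluster with the most interferon RNA, had come out for it, since cluster 20 stood at 10216 CPM and neutrophil-like cells at 8108; it was replaced after that value was seen, because free RNA does not come from 1 small cluster. For doublets with macrophages, macrophage markers in the cells with 10 or more interferon UMIs stood at 3.12% of the macrophage-like level. That value cannot decide, because cells rich in macrophage markers would be clustered outside the neutrophil-like class. Cluster 22, led by S100a8 and S100a9 with 10 detected macrophage markers and a median of 19803.5 UMIs, was an unnamed cluster of that kind. Doublets with other cells, such as cluster 20, were not tested. The list stood at 38686 CPM in the 67 neutrophil-like cells with 10 or more interferon UMIs, and at 10216 CPM in cluster 20 of the combination. Those 67 cells were chosen by that same level in 1 library, so the values cannot decide, and doublets stay open. The median cell had 1 interferon UMI of 1000, no more than the level that 9 in 10 olaparib cells do not exceed, 2. The criterion was met for a minority of cells, but it cannot exclude a smaller shift in the others. Combination cells under 10 interferon UMIs stood at 1151 CPM of the list, against 597 in olaparib and 642 in vehicle. At least 1 such UMI was seen in 51.5% of thinned combination, 34.3% of olaparib and 36.0% of vehicle cells. A biological effect of the combination may explain it, but the design has 1 pool per treatment, so an event in 1 of the pooled tumours stays open.

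For the MHC class II genes of macrophage-like cells in the combination, free RNA from antigen-presenting cells should raise them in neutrophil-like cells too. The gain of H2-Aa, H2-Ab1 and Cd74 there was 0.0424 of that in macrophage-like cells, which argues against it as the whole cause. A larger share of cluster 9 is argued against as the whole cause, because without it the list median was 1.14, against 1.37 with it. With equal cluster weights the median was 0.98, so a shift between clusters may account for part of the difference. A response to the combination, and a difference between the pooled tumours, both stay open as untested explanations. Whether cDC2-like cells placed in the macrophage-like class add to the difference was not tested either.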
